A study of Homo sapiens with 4 samples.

How the data were processed

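RNA of TMD8 cells treated with 2 µM AZD1480 for 1, 3, 6 or 24 h was hybridised together with RNA of DMSO-treated TMD8 cells on 4 Agilent Whole Human Genome arrays, 1 per time. Per the labels' protocols, total RNA was extracted with TRIzol, cleaned on columns, amplified and labelled, with Cy5 for AZD1480 and Cy3 for DMSO on every array. All 4 arrays were on 1 slide and were read in 1 scan, so no batch of slide or scan could be tested, and all 4 samples carry replicate number 1, which pairs nothing.

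Per the file headers, spots were read with Agilent Feature Extraction 10.1.1.1, and the probe coordinates are on hg18 (NCBI build 36). The deposited scanner files hold for each spot the mean intensity and the median local background intensity of both channels, which are raw. They also hold the processed intensity, background-subtracted and dye-normalized by that software, and a log10 ratio of processed Cy5 over Cy3, per the file headers. The value table deposited by the authors was set against the scanner files. It equals log10 of processed Cy5 over Cy3 within 5.0e-04, with 3 decimals, was not centred and has the same direction. Its medians over all spots were -0.099, -0.035, -0.055 and -0.034 at 1, 3, 6 and 24 h. Agilent's ratio was exactly 0 at 16434, 12534, 11449 and 11256 spots. The number of value columns that belong to no sample was 0.

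Ratios were computed from the spot signals in R 4.3.3 with limma 3.58.1. The background was corrected with normexp and an offset of 50, which draws ratios of dim spots towards 0, and each array was normalized by loess, which assumes that genes of one brightness do not shift one way on balance. Control spots and spots with an outlier mark had weight 0 in loess and were then left out, and saturated spots stayed in. Of 43376 spots that were not controls, 357, 156, 183 and 159 were outliers, and 2, 0, 0 and 5 were saturated. Spots of one probe were averaged, and 198 probes with replicate spots that passed the filter given next were used for the spread between spots. A probe was kept if it was well above background in at least 1 channel on at least 2 arrays and had a value on every array, which left 24749 of 41000. A further 201 probes met the first condition but lacked a value on an array and were dropped. Each gene was represented by its probe with the highest mean intensity. Probes were named through their RefSeq accession from a table of GRCh38.p14 genes, used for names only, for 23680 probes, and by the name in the file for the other 17320. Of 18516 genes tested, 12113 had such a current symbol. Several measured probes were available for 4745 genes, and in 1917 of these the probes differed in sign. Among the called genes the numbers were 285 and 108.

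The mean log2 ratio over the 4 times was tested against 0 with limma (lmFit and eBayes, two-sided, 3 residual degrees of freedom), and the change with time as a slope on log2 hours with 2 residual degrees of freedom. Both were adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05. The times served as the replicates, so the SD of a mean includes any change with time. Gene lists were tested with camera at a preset correlation of 0.01 between genes, which compares a list with the other genes, adjusted over 27 lists. Camera with an estimated correlation and fry, which tests whether a list's own genes move one way on balance, were run beside it. Camera with an estimated correlation uses only the residual degrees of freedom of the fit. A call lost with it therefore does not by itself show that correlation between genes made the call. Where the estimate lay far above the preset 0.01, correlation between genes stays a possible reason for the loss. For single times, a list's median was placed among 10000 random lists of the same size matched on mean intensity in 20 bins. Where a channel was not well above background, the fold is a bound: the bright channel against the higher of the dim value and the lowest signal among probes well above background, after loess and Aquantile, and open to dye bias. Where the dim value was the higher, the fold is the measured ratio and no firm minimum. The number of arrays, 4, limits the precision of every mean.

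The gene lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. The rule took the 12 largest decreases and 12 largest increases that passed, had one sign on all arrays and were well above background in at least 1 channel on each. It added the 6 genes with the smallest p for slopes in each direction, since none passed, up to 4 passing members per list or 2 that did not pass, the 3 largest changes per direction and time among genes well above background in both channels, and 21 genes of JAK-STAT and NF-kB signalling whatever their values. Genes known only by clone, locus or probe names were left out, and the rule gave 118 genes. Some of these genes and 1 gene list are not reported here. The alternatives changed the background correction, the normalization, the source of the ratio, the filter, the probe rule, the variance model, the time scale, the list test and the arrays in the fit. A fit of the 3 h and 24 h arrays alone and a term that set the 1 h and 6 h arrays apart were added after seeing the data.

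The procedure was tested on simulated data of 18516 genes. In the test of the mean, 20.9% of genes changed 1.5-fold, 88.1% changed 2-fold and 100% changed 4-fold were called, with 9 unchanged genes. In the test of change with time, 28.4%, 95.5% and 100% of genes changed 4, 16 and 64-fold over the times were called, with 7 unchanged genes. A shifted list of 38 genes was called in both list tests, with 0 other lists in the mean and 1 in the change with time. The noise in these tests was drawn independently for each gene and array. It held no dye effect, shared DMSO sample, likeness of arrays or correlation between genes, so these shares and counts hold only for such noise. From simulated spot signals, all changed genes had the right direction, and the median of the true minus the found log2 ratio was -0.05, -0.07 and -0.05 at 1.5, 2 and 4-fold. A genome sequence was not used here.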

Results

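Gene expression was measured in TMD8 cells treated with AZD1480 for 1, 3, 6 and 24 h. TMD8 is an established cell line of the activated B cell-like form of diffuse large B cell lymphoma, a lymphoma known for autocrine cytokine signalling through Janus kinases (JAK) and STAT3 and for chronic NF-kB activity. AZD1480 is an inhibitor of JAK1 and JAK2 and was used at 2 µM. On each of 4 arrays, RNA of treated cells carried Cy5 and RNA of cells given the solvent DMSO carried Cy3, so each ratio is AZD1480 over DMSO. Each time had 1 array, and the labels do not say whether the DMSO RNA was one sample or was collected at each time. Of 41000 probes per array, 58.2%, 59.3%, 59.1% and 63.9% were well above background in the treated channel at 1, 3, 6 and 24 h, and 39.4%, 44.8%, 43.8% and 44.0% in the DMSO channel. Spots of one probe on one array had a median SD of 0.12 (log2) at 1 h and of 0.05, 0.04 and 0.04 at the later times.

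The first comparison asked which genes differed between AZD1480 and DMSO over the 4 times together in this cell line. With a single inhibitor at a single dose, dependence of these genes on JAK activity itself was not tested. The 12 named genes with the largest decreases were 2.61 to 4.14-fold lower on average. They included SOCS3, a feedback inhibitor of JAK signalling, with a mean log2 ratio of -2.01 ± 0.65 (SD over the times, n = 4). The cytokine genes IL6 and IL10, which signal through JAK and STAT3, fell to -1.64 ± 0.51 and -1.39 ± 0.52. JUN, a subunit of the transcription factor AP-1, fell to -1.87 ± 0.52, and CD274, which encodes an immune checkpoint ligand, to -1.64 ± 0.66. The interferon-induced gene IFIT1 fell to -1.74 ± 1.15, with -0.13 at 1 h and -2.57 at 24 h. The others were DEPP1 (-2.05 ± 0.48), PHLDA1 (-1.70 ± 0.48), PTGDR, a prostaglandin receptor gene (-1.61 ± 0.57), the ETS factor gene SPIC (-1.58 ± 0.90), TMSB4X, which encodes an actin-binding peptide (-1.41 ± 0.49), and FCRL4, an Fc receptor-like gene of B cells (-1.39 ± 0.90). As the rule for these genes required, all 12 passed and had a negative ratio on each array, with adjusted p from 0.0172 to 0.0449 (limma). Of 6 of these genes with several probes, 2 had probes that differed in sign, since the second probe of DEPP1 had a mean of 0.13 and the highest of 4 PHLDA1 probes 0.25. The second SOCS3 probe had a mean of -0.17 and the second TMSB4X probe -0.49.

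On the hg18 build, the probe for SOCS3 lies on chromosome 17 from 73864722 to 73864781, that for IL6 on chromosome 7 from 22737732 to 22737791 and that for IL10 on chromosome 1 from 205008017 to 205008076. The JUN probe lies on chromosome 1 from 59020317 to 59020376, the CD274 probe on chromosome 9 from 5460098 to 5460157 and the IFIT1 probe on chromosome 10 from 91153418 to 91153477. The DEPP1 probe lies on chromosome 10 from 44791716 to 44791775. For the genes that rose, the EEF1A1 probe lies on chromosome 6 from 74284515 to 74284574, the CX3CL1 probe on chromosome 16 from 55976366 to 55976425 and the CD79B probe on chromosome 17 from 59360885 to 59360944.

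The 12 named genes with the largest increases were 2.19 to 4.12-fold higher on average, with adjusted p from 0.0181 to 0.0496 (limma). The largest was ALYREF, an mRNA export factor, with a mean of 2.04 ± 1.47 (n = 4). CTNNB1, which encodes beta-catenin, rose to 1.81 ± 1.12, the chemokine gene CX3CL1 to 1.50 ± 0.62 and the Wnt ligand gene WNT10A to 1.37 ± 0.56. CD79B, a subunit of the B cell receptor, rose to 1.33 ± 0.69. FAM43A (1.33 ± 0.93), the protease gene CAPN1 (1.27 ± 0.85), CLINT1 (1.23 ± 0.86), KREMEN2 (1.16 ± 0.74), the splicing factor gene SRSF6 (1.16 ± 0.80), RNF122 (1.14 ± 0.31) and the ribosomal protein gene RPL35 (1.13 ± 0.79) completed the group. FAM43A was not well above background in DMSO at 1 h. Its ratio there, 3.09-fold higher with AZD1480, is the measured value over a dim DMSO signal and no firm minimum. Of 8 of the 12 with several probes, CAPN1 had probes that differed in sign, from -0.45 to 1.27. Other probes had means closer to 0 than those used, at 0.67 for CTNNB1, 0.07 and 0.23 for CX3CL1, 0.23 for CLINT1 and 0.21 for RPL35. For 9 of the 12 genes the ratio was larger on the 1 h and 6 h arrays than on the 3 h and 24 h arrays, which was so for 0 of the 12 largest decreases. ALYREF, for example, had log2 ratios of 3.02, 0.70, 3.57 and 0.87 at 1, 3, 6 and 24 h. Its log2 signal was 14.30, 14.15, 14.73 and 14.31 in the treated channel and 11.28, 13.45, 11.15 and 13.43 in the DMSO channel, so most of the difference between the arrays lay in DMSO. On the 3 h and 24 h arrays alone its mean was 0.79 (adjusted p = 0.0559).

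Over all 18516 genes tested, 456 were lower and 519 higher with AZD1480 (limma, adjusted p up to 0.05), and all 975 had the same sign on the 4 arrays. At an unadjusted p under 0.05 there were 6076 genes, against 925.8 for chance. The lowest adjusted p was 0.0172, so calls lay close to the threshold. The 1 h and 6 h arrays resembled each other more than the others did, with a correlation across genes of 0.65, against 0.35 to 0.54 for the other pairs. On the 3 h and 24 h arrays alone, 71 genes were lower and 24 higher, and of the 12 largest decreases and 12 largest increases 9 and 3 passed. Of all named genes reported here that passed, 14 of 37 lower and 4 of 28 higher genes passed on those arrays alone. The ratio was larger on the 1 h and 6 h arrays than on the 3 h and 24 h arrays for 19 of the 28 higher genes, against 3 of the 37 lower. No single array could be left out without losing most calls. The counts of lower and higher genes were 46 and 5 without the 1 h array, 1 and 0 without 3 h, 26 and 3 without 6 h, and 86 and 10 without 24 h. With median centring in place of loess the median of all genes moved to 0.78, 8.46% of calls were lower against 46.8%, and 23 of 68 genes that passed among those given by the rule for named genes changed sign. No array had swapped dyes, so a gene-specific dye effect adds to these means, and if the DMSO RNA was one sample the test leaves out its own spread. The labels name no separate cultures, so p-values measure only the spread between these samples, which may be technical.

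**Figure D1:**
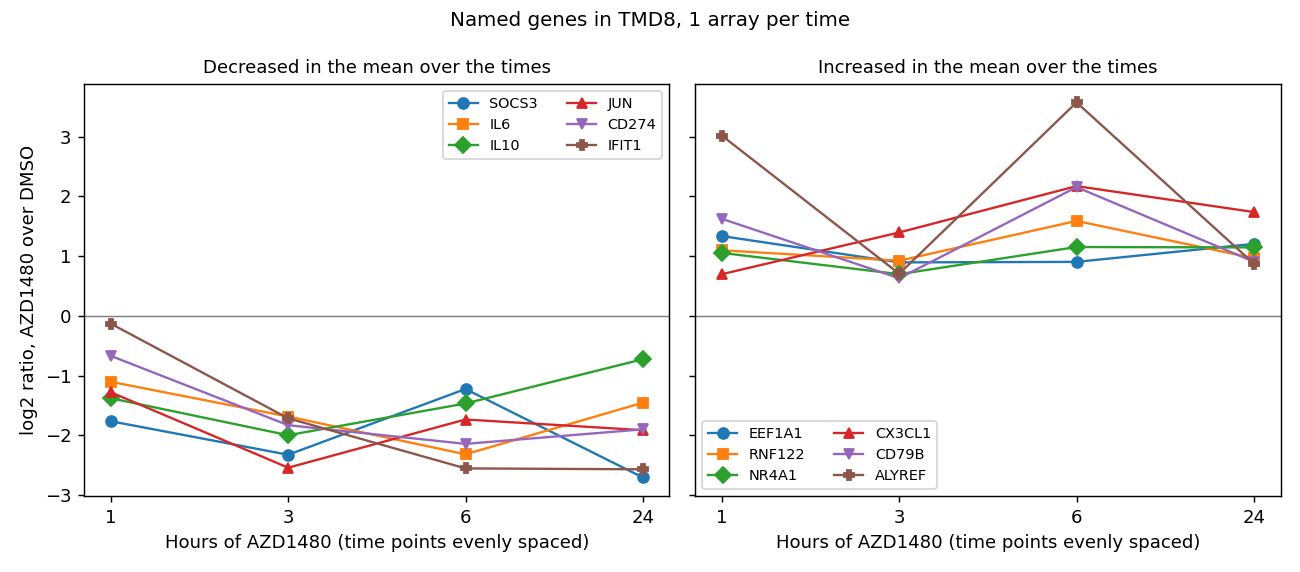
Log2 ratio of AZD1480 over DMSO (y axis) against hours of treatment (x axis, time points evenly spaced) for 6 genes that decreased (left) and 6 that increased (right) in the mean over the times; each point is 1 array, with no error bar. SOCS3 lies between -1.23 and -2.71, whereas ALYREF is at 3.02 and 3.57 at 1 h and 6 h and below 1 at the other times.

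Genes of JAK-STAT feedback and STAT3 targets fell as a list over the 4 times (camera, adjusted p = 0.00516, median -0.18). With the estimated correlation between genes, 0.27 against the preset 0.01, the adjusted p was 0.988. Of 27 measured members 5 fell and 1 rose, or 7 and 1 adjusted over the list alone. Beside SOCS3, IL6 and IL10, these were the germinal centre repressor gene BCL6 (-0.68 ± 0.21), the survival gene MCL1 (-0.51 ± 0.18) and, rising, the receptor gene IL10RA (0.58 ± 0.19). The list's median was 0.13 at 1 h, -0.55 at 3 h, -0.02 at 6 h and -0.43 at 24 h, and only the 3 h and 24 h values lay at percentile 0 of 10000 random lists matched on intensity. On those 2 arrays alone the adjusted p was 4.2e-08 with a median of -0.50, and without the 3 h array it was 0.164. The call was also lost with the scanner software's own ratios (adjusted p = 0.0832), the authors' deposited ratios (adjusted p = 0.0962), no filter on dim probes (adjusted p = 0.0585) and fry (adjusted p = 0.368). With median centring in place of loess the median turned to 0.62, which is -0.16 relative to all genes, with an adjusted p of 0.337.

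Interferon-stimulated genes also fell as a list (camera, adjusted p = 9.7e-04, median -0.21). The adjusted p was 0.988 with the estimated correlation, which was 0.35 against the preset 0.01. Of 38 measured members 5 fell and 0 rose, against 11 and 4 adjusted over the list alone. Beside IFIT1 these were PLSCR1 (-0.73 ± 0.43), XAF1 (-0.65 ± 0.35), SAMD9 (-0.53 ± 0.22) and OASL (-0.48). The highest of 4 SAMD9 probes had a mean of 0.16. The call was lost without the 24 h array (adjusted p = 0.0942), with only probes well above background in both channels on all 4 arrays (adjusted p = 0.0612) and with fry (adjusted p = 0.434), and was kept on the 3 h and 24 h arrays alone (adjusted p = 4.5e-06). With median centring the median turned to 0.59, which is -0.18 relative to all genes, with an adjusted p of 0.252, and the means of PLSCR1 and SAMD9 turned above 0.

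Housekeeping and ribosomal protein genes were higher as a list (camera, adjusted p = 8.3e-04, median 0.38). With the estimated correlation, 0.047, the adjusted p was 0.988, a value that every list had in this version of the test. Of 31 measured members 6 rose and 0 fell, and 15 rose adjusted over the list alone. The translation factor gene EEF1A1 rose to 1.08 ± 0.22 (n = 4), RPL18 to 0.83 ± 0.30, RPL8 to 0.78 ± 0.37 and RPL6 to 0.57. The second RPL18 probe had a mean of 0.15. The median was 0.35, 0.22, 0.44 and 0.25 at 1, 3, 6 and 24 h. The call was lost with the scanner software's own ratios (adjusted p = 0.556) and with the authors' deposited ratios (adjusted p = 0.492). With fry the adjusted p was 0.0521.

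The other 24 lists were not called in the mean over the times, but several held genes that passed alone. In the apoptosis and BCL2 family list (adjusted p = 0.178), 4 of 29 members fell and 0 rose, or 4 and 1 adjusted over the list alone. They were the pro-apoptotic gene BBC3 (-1.21 ± 0.41), the inhibitors of apoptosis BIRC3 (-1.10 ± 0.33) and BIRC2 (-0.74 ± 0.13), and MCL1. Of 3 BBC3 probes, one had a mean of 0.78. This list was called lower on the 3 h and 24 h arrays alone, just under the threshold and from 2 arrays (adjusted p = 0.0495), and over the 4 arrays its adjusted p with an estimated correlation was 0.988. Among 33 NF-kB targets, 3 fell (IL6, IL10 and BIRC3) and 0 rose, or 5 and 4 adjusted over the list alone. Among 26 immediate early genes, JUN, EGR2 (-1.35 ± 0.72) and KLF6 (-1.18 ± 0.26) fell while NR4A1 rose (1.01 ± 0.21), and the counts adjusted over the list alone were 5 and 2. The highest of 3 KLF6 probes had a mean of 0.01. NR4A1 was not well above background in DMSO at 6 h. Its ratio there, 2.22-fold higher, is the measured value over a dim DMSO signal and no firm minimum. Among 19 germinal centre B cell genes 4 fell, BCL6, LMO2 (-1.06 ± 0.70) and ELL3 (-0.92 ± 0.39) among them, and 0 rose, or 4 and 3 adjusted over the list alone. With median centring in place of loess, where the median of all genes was 0.78, the means of BBC3, BIRC2, BIRC3, MCL1, KLF6, BCL6, LMO2 and ELL3 turned above 0.

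B cell receptor and B cell identity genes gave 3 increases and 1 decrease among 27 members, or 7 and 2 adjusted over the list alone. CD79B and CD79A (0.65 ± 0.28) rose, whereas the kinase gene LYN fell (-0.58 ± 0.24). The list's median was highest on the 1 h and 6 h arrays, at 0.30 and 0.54, against -0.03 at 3 h and 0.19 at 24 h. BCL10 (-0.74 ± 0.27) and TLR1 (-0.43 ± 0.09) also fell, and IRF5 rose (0.46 ± 0.04). The second BCL10 probe had a mean of 0.49. Among 31 heterochromatin and histone modifier genes, the demethylase genes KDM4C (-0.64 ± 0.21) and KDM4A (-0.63 ± 0.34) and the DNA dioxygenase gene TET2 (-0.69 ± 0.28) fell. UHRF1, a reader of methylated DNA, rose (0.93 ± 0.42), and the counts adjusted over the list alone were 3 and 3. Among 39 MYC-driven genes of ribosome biogenesis and nucleotide synthesis, 5 fell and 2 rose, or 6 and 9 adjusted over the list alone. MYC itself fell to -0.58 ± 0.30 with an adjusted p of 0.0496, NIP7 fell to -0.67 ± 0.35, and RRP12 (0.83 ± 0.43) and RRP9 (0.60 ± 0.31) rose. Of 19 genes of MHC class I and antigen processing, TAPBP (1.11 ± 0.75) and HLA-C (0.74 ± 0.21) rose and PDIA3 fell (-0.76 ± 0.22), or 7 and 1 adjusted over the list alone. The ratios of CD79B, CD79A, UHRF1, RRP12, RRP9, TAPBP and HLA-C were larger on the 1 h and 6 h arrays than on the 3 h and 24 h arrays. On the 3 h and 24 h arrays alone none of these genes passed. The other 2 TAPBP probes had means of 0.13 and 0.20, and the other 2 MYC probes -0.11 and -0.12. With median centring, where the median of all genes was 0.78, the means of LYN, BCL10, TLR1, KDM4C, KDM4A, MYC, NIP7 and PDIA3 turned above 0.

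Few genes of the cell cycle passed. CDKN1B, which encodes a cyclin-dependent kinase inhibitor (-0.79 ± 0.28), and CCNG2 (-0.55 ± 0.20) fell among 24 cell cycle inhibitor and quiescence genes, or 5 lower and 3 higher adjusted over the list alone. E2F2 (0.75 ± 0.33) and UHRF1 rose among 34 S phase genes, and HJURP (0.56 ± 0.27) among 35 genes of G2 and M phase. Adjusted over the list alone these were 2 and 0 increases, with 0 decreases in either. Among 24 p53 targets only BBC3 fell (5 lower and 4 higher adjusted over the list alone). Among 28 glycolysis and hypoxia genes only PFKFB3 fell (-0.89 ± 0.40, and 1 adjusted over the list alone). Among 27 genes of the ATF4 response VLDLR rose, at least 1.51-fold since DMSO was not well above background, with 9 higher and 1 lower adjusted over the list alone. STIP1 rose (0.73 ± 0.45) among 19 heat shock genes, also adjusted over the list alone. Of 23 chemokine and cytokine genes IL6 and IL10 fell (3 lower and 2 higher adjusted over the list alone). In the JAK-STAT pathway components, 1 of 24 members fell (PTPRC, -0.50 ± 0.16) and 1 rose (IL10RA), or 2 and 5 adjusted over the list alone. The second probes of CCNG2 and E2F2 differed in sign from those used, with means of 0.0014 and -0.19. The second CDKN1B probe had a mean of -0.13, and one PFKFB3 probe -0.02. With median centring, where the median of all genes was 0.78, the means of CDKN1B, CCNG2, BBC3, PFKFB3 and PTPRC turned above 0.

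No member passed in 3 further lists of this cell or in 3 lists of other cell types. Among 24 cholesterol synthesis genes MVD had 0.80 ± 0.63 and LSS 0.65 ± 0.47, with 4 higher adjusted over the list alone. SDC1 (0.50 ± 0.22) and PDIA4 (0.53 ± 0.53) led 24 plasma cell and secretory genes, and CIITA (0.46 ± 0.36) and HLA-DRB5 (0.40 ± 0.37) led 15 MHC class II genes, with 0 adjusted over either list alone. Probes of CIITA differed in sign. Of markers of T and NK cells 9 of 22 were measured, with CD5 at 0.98 ± 0.69 and 1 higher adjusted over the list alone. Of myeloid markers 5 of 20 were measured, with MS4A7 at -0.47 ± 0.24 and 1 lower and 2 higher adjusted over the list alone. Of fibroblast, endothelial and epithelial markers 11 of 18 were measured, with THY1 at 0.35 ± 0.11 and 0 adjusted over the list alone. This last list was called higher by fry (adjusted p = 0.0280), against 0.954 by camera. CD7, ITGAM and COL1A1 were not well above background in DMSO. Median, mean and direction of the test differed in sign in 10 of the lists that were not called, such as the NF-kB targets with a median of 0.02 and a mean of -0.04.

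The kinases and most of their immediate signalling genes did not pass. JAK1 had a mean of -0.44 ± 0.31, JAK2 -0.22 ± 0.11, JAK3 -0.20 ± 0.89 and TYK2 0.70 ± 0.49, with adjusted p of 0.0774, 0.171, 0.658 and 0.0575 (limma). STAT3 was at -0.44 ± 0.85. The feedback genes SOCS1 (-0.45 ± 0.55) and CISH (-0.24 ± 0.15) and the STAT targets PIM1 (0.11 ± 0.40), PIM2 (0.71 ± 0.70) and BCL3 (-0.47 ± 0.35) were among the genes that missed the threshold. IRF4 (0.43 ± 0.58), MYD88 (0.40 ± 0.24), PRDM1 (-0.20 ± 0.27), TNFAIP3 (-0.03 ± 0.26) and NFKBIA (-0.42 ± 0.39) did not pass. Probes of STAT3, JAK3, SOCS1, CISH, IRF4 and TNFAIP3 differed in sign. The means of JAK1, JAK2, JAK3, STAT3, SOCS1, CISH, BCL3, PRDM1, TNFAIP3 and NFKBIA turned above 0 with median centring, where the median of all genes was 0.78. Those of JAK3, BCL3, TNFAIP3 and NFKBIA lay above that median and the others below it.

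The second comparison asked whether the ratio changed with the time in AZD1480, as a slope per doubling of hours. Interferon-stimulated genes fell with time as a list (camera, adjusted p = 8.5e-12), with 35 of 38 slopes below 0 and a median slope of -0.11. The adjusted p was 0.363 with an estimated correlation and 0.0291 with fry, and the call was kept without each array in turn. The list's median ratio was -0.05 at 1 h and 3 h, -0.31 at 6 h and -0.45 at 24 h. JAK-STAT pathway components fell with time (adjusted p = 0.00354, 19 of 24 slopes below 0, median -0.05), as did JAK-STAT feedback and STAT3 targets (adjusted p = 0.0272, 21 of 27 slopes below 0, median -0.06). The feedback list showed no steady fall. Its median change was -0.15 from 1 h to 6 h, with 17 of 27 members below 0, but 0.09 from 3 h to 24 h, with 20 above 0. The pathway components did not stand apart within these pairs of arrays. Their median change was -0.03 from 1 h to 6 h (percentile 33.5 of matched random lists) and -0.06 from 3 h to 24 h (percentile 18.2). NF-kB targets rose with time (adjusted p = 0.00354, 24 of 33 slopes above 0, median 0.06), with median ratios of -0.01 at 1 h, -0.25 at 3 h, 0.24 at 6 h and 0.19 at 24 h, which is a low at 3 h and no steady rise. With median centring the median slope of the NF-kB targets was -0.02, still called rising against the other genes. For these 3 lists the adjusted p was 0.922 with an estimated correlation and 0.947 with fry. The estimated correlation was 0.092 for the pathway components, 0.30 for the feedback list and 0.35 for the NF-kB targets, against the preset 0.01. The pathway components lost the call without the 1 h array (adjusted p = 0.173) or the 24 h array (adjusted p = 0.323), without background correction (adjusted p = 0.196), with the scanner software's own ratios (adjusted p = 0.114) and with the authors' deposited ratios (adjusted p = 0.105). The feedback list lost it without 1 h (adjusted p = 0.662) or 24 h (adjusted p = 0.0905), and under 5 changes of processing: no background correction (adjusted p = 0.196), no filter (adjusted p = 0.0843), only probes well above background throughout (adjusted p = 0.162), probe means (adjusted p = 0.0944) and scale normalization (adjusted p = 0.148). The NF-kB targets lost it without 3 h (adjusted p = 0.0998) or 24 h (adjusted p = 0.995), with the scanner software's own ratios (adjusted p = 0.126) and with the authors' deposited ratios (adjusted p = 0.164). With a term that set the 1 h and 6 h arrays apart, the adjusted p was 5.6e-11 for the interferon-stimulated genes, 5.7e-07 for the NF-kB targets, 0.172 for the pathway components and 0.870 for the feedback list.

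No single gene passed the test of change with time (limma, lowest adjusted p 1.00, with 593 genes at an unadjusted p under 0.05 against 925.8 for chance). Adjusted over the list alone, 2 pathway components, 1 gene of the feedback list and 1 of the chemokine and cytokine list passed, and 0 in any other list. Without the 6 h array 19 genes passed. The smallest p among falling slopes belonged to CXCL13, a B cell chemokine gene, at -0.58, -1.09, -2.37 and -4.01 over the 4 times. Those next to it were TMED9, DENND3, MPHOSPH8, STAT3 and FBXO34, with STAT3 at 0.62, -0.57, -0.37 and -1.44. With median centring, where the median of all genes was 0.78, their means over the times all turned above 0. Among rising slopes RSPH1 had 0.00, 0.37, 0.84 and 2.37, followed by TESC, OLFML2A, TCFL5, ZNF354A and HTR3A. In DMSO, ZNF354A and HTR3A were not well above background. The second TCFL5 probe had a mean of 0.19 against 0.46.

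**Figure D2:**
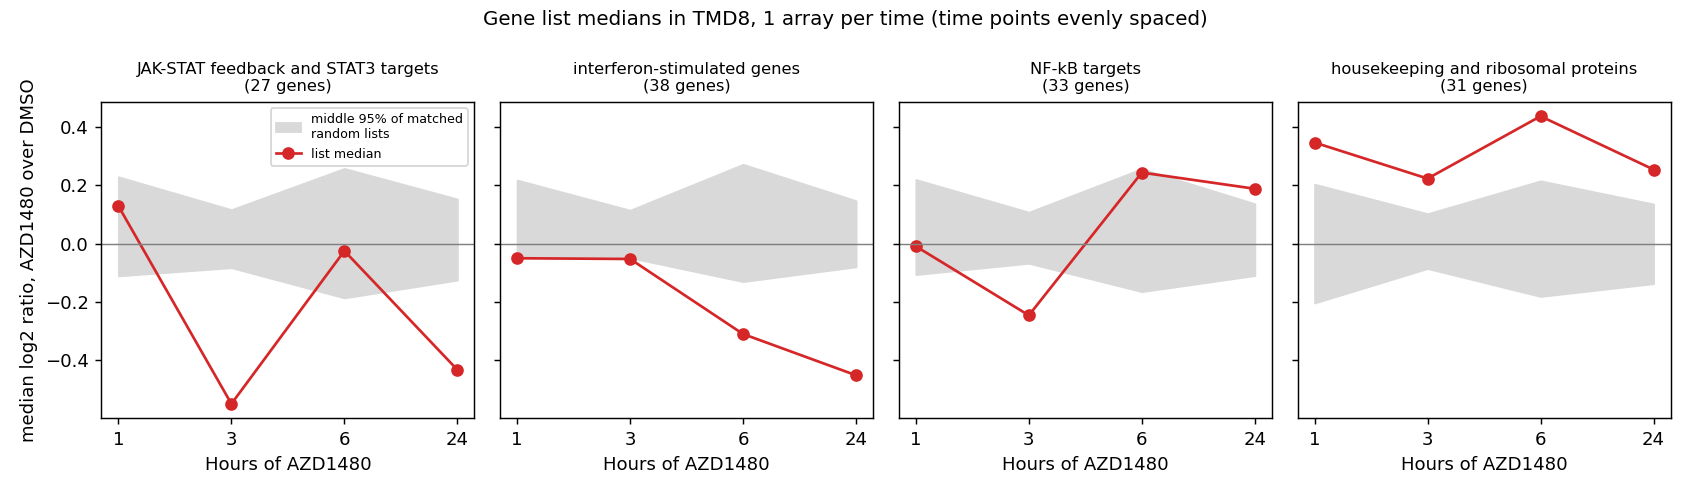
Median log2 ratio of AZD1480 over DMSO (y axis) against hours of treatment (x axis) for 4 gene lists; points are list medians on 1 array each and the grey band holds the middle 95% of 10000 random lists matched on intensity. Interferon-stimulated genes move from -0.05 at 1 h to -0.45 at 24 h, and housekeeping genes stay between 0.22 and 0.44. With median centring in place of loess the medians over the times turn to 0.59 for interferon-stimulated genes and 0.62 for the JAK-STAT feedback list, below the 0.78 of all genes.

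Each time was also described alone, with no test because it had 1 array. At 1 h, 163 genes were at least 2-fold lower and 301 higher, at 3 h 101 and 66, at 6 h 331 and 1188, and at 24 h 187 and 162. The direction with more genes turned with the processing at 3 h and 24 h. The scanner software's own ratios gave 294 lower and 1372 higher at 3 h and 403 and 1943 at 24 h, the authors' deposited ratios 292 and 1368, and 404 and 1941. An offset of 16 gave 120 and 256, and 212 and 389, and median centring 11 and 4771, and 50 and 5697. Without background correction the counts were 71 and 6 at 3 h and 130 and 54 at 24 h. Among genes that the scanner software marked as well above background in both channels, the lowest ratios at 1 h belonged to EEFSEC (-3.08), ECHDC2 (-2.50) and ANKIB1 (-2.28) and the highest to NDUFB5 (4.58), ALYREF (3.02) and MED6 (2.96). The 1 h DMSO signals of NDUFB5 (5.90) and MED6 (4.66) were below that of CD7 (7.21), which was not well above background, so these 2 ratios rest on a DMSO signal near the floor. At 1 h the second MED6 probe was at 0.0036 and the second ECHDC2 probe at -0.08. At 3, 6 and 24 h EEFSEC was at 0.20, 0.38 and 0.49 and ECHDC2 at 0.39, 0.10 and 0.07. Both were well above background in DMSO on the 1 h array only. NDUFB5 was at -0.05 at 3 h and MED6 at 0.08, and with the authors' deposited ratios their means over the times turned from 0.81 and 0.78 to -0.76 and -0.47. At 3 h JUN (-2.54), SOCS3 (-2.33) and DEPP1 (-2.31) were lowest and CX3CL1 (1.40), FCGRT (1.39) and RPL18 (1.19) highest. At 6 h RNF183 (-2.79), IFIT1 (-2.56) and CXCL13 (-2.37) were lowest and ALYREF (3.57), CDC42EP5 (3.25) and LCE5A (3.08) highest. At 3 h and 24 h CDC42EP5 was at 0.03 and -0.36 and LCE5A at 0.17 and -0.13, and their DMSO signals were 11.18 and 10.42 at 6 h against 14.21 and 13.50 at 3 h. At 24 h CXCL13 (-4.01), SOCS3 (-2.71) and TAF5L (-2.70) were lowest and RSPH1 (2.37), BSPRY (1.80) and OLFML2A (1.75) highest. Probes of ANKIB1, TAF5L and FBXO34 differed in sign, and at 6 h the second RNF183 probe was at -1.18.

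**Figure D3:**
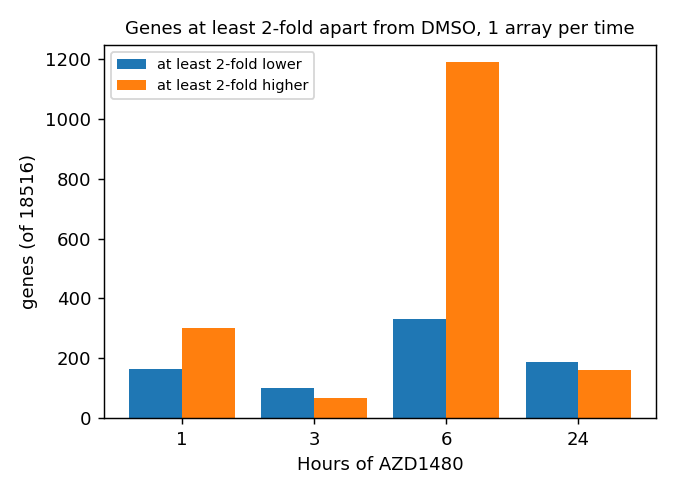
Number of genes (y axis, of 18516) at least 2-fold lower or higher with AZD1480 than with DMSO against hours of treatment (x axis), on 1 array per time. The 6 h array has the most, with 1188 higher and 331 lower, and the 3 h array the fewest. With the scanner software's own ratios the higher genes outnumber the lower at 3 h and 24 h as well, by 1372 to 294 and 1943 to 403.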

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

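In the next paragraph, the tests of the likeness of arrays and of a dye effect were chosen after the results were seen. The ratio of AZD1480 over DMSO differed between the times in 4 gene lists, each by the test of change with time (camera on the limma slope). Interferon-stimulated genes fell with time (adjusted p = 8.49e-12, 35 of 38 slopes below 0), JAK-STAT pathway components fell (adjusted p = 0.00354, 19 of 24), NF-kB targets rose (adjusted p = 0.00354, 24 of 33 slopes above 0) and JAK-STAT feedback and STAT3 targets fell (adjusted p = 0.0272, 21 of 27 below 0). From 3 h to 24 h the feedback list did not fall, with a median change of 0.09 and 20 of 27 members above 0. The pathway components had a median change of -0.03 from 1 h to 6 h and -0.06 from 3 h to 24 h. These lay at percentiles 33.5 and 18.2 of matched random lists, so no clear fall was seen inside either pair of arrays. With an estimated correlation between genes the adjusted p was 0.363 for the interferon-stimulated genes and 0.922 for the other 3 lists. For those 3 the estimate was 0.092 (pathway components), 0.35 (NF-kB targets) and 0.30 (feedback list), against the preset 0.01.

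The fall of the interferon-stimulated genes was weighed further. It was not a by-product of the likeness of the 1 h and 6 h arrays, since the list also fell inside both pairs of like arrays (median change -0.26 from 1 h to 6 h and -0.34 from 3 h to 24 h), and the higher of their percentiles among 10000 matched random lists was 0.05. A gene-specific dye effect that was the same on every array, or the level of one DMSO sample, would cancel between times. The list's median at 24 h minus that at 1 h was -0.40. This difference restates the fall and spans both kinds of array, and a dye effect that differed between arrays was not tested. A rise of these genes in DMSO samples taken at each time was argued against by the channels: from 3 h to 24 h the median Cy5 change was -0.39, at percentile 0 of matched random lists, and the median Cy3 change 0.02, at percentile 42.3. The fall may therefore reflect a slow loss of interferon-type expression in cells kept in AZD1480, as a hypothesis found and tested on the same 4 arrays. Time in culture stays open if the DMSO RNA was one sample. The call is lost with the estimated correlation between these genes, but that estimate was -0.0062, below the preset 0.01. That version also uses only 2 residual degrees of freedom, so the loss does not show that correlation made the call.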

How the results depend on the processing

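The fit of the 3 h and 24 h arrays alone and the term that set the 1 h and 6 h arrays apart were chosen after seeing the data. For every value below that moved, lost its call or turned, the cause was not tested. No paired analysis was possible because each time had 1 array and all arrays carry the same replicate number.

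Of 68 genes that passed among those given by the rule for named genes, all kept their direction under each alternative that measured them except median centring without loess, where 23 turned. All called genes had one sign on the 4 arrays, so some of these alternatives could not turn a mean. These were the fits with fewer arrays or an added term, scale normalization and the variance model. The number still passing ranged from 68 (scale normalization) through 28 (no background correction) and 18 (3 h and 24 h arrays) to 0 (without 3 h). Against 456 lower and 519 higher genes, there were 146 and 65 without background correction (69.2% lower against 46.8%), 1138 and 12319 with median centring (8.46%), 785 and 1422 with scale normalization (35.6%), 95 and 15 with a slope in the model (86.4%), 71 and 24 on the 3 h and 24 h arrays (74.7%), and 1109 and 2579 with the term for the 1 h and 6 h arrays (30.1%). Differences between arrays alone, planned to remove a dye effect, are the test of change with time and estimate no mean, and they gave 0 and 0. The higher genes numbered 1389 with Agilent's ratios (24.6% lower), 1340 with the deposited ratios (25.1%) and 142 with probes well above background in both channels on all 4 arrays (68.2%). Leaving out 1 array gave 1 to 86 lower and 0 to 10 higher genes. Genes in counts of 5 or fewer, chosen after their values were seen, were CX3CL1, CA13, RASD1, XRCC6BP1 and an Ensembl transcript without 1 h, a sequence tag without 3 h, and EEF1A1, RNF122 and WNT10A without 6 h. Other settings stayed within 1.5 times. For change with time, leaving out 1 array gave 0 to 19 genes, and the term gave 2, CXCL13 and an Ensembl transcript.

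The lists lower in the mean (2) numbered 0 with median centring, 1 with Agilent's ratios, 1 with the deposited ratios, 1 without a filter, 1 with the strict filter, 0 with an estimated correlation and 0 with fry, and 1 to 2 without 1 array. Lists higher (1) numbered 11 with median centring, and 0 with Agilent's ratios, 0 with the deposited ratios and 0 with an estimated correlation. With fry the number stayed at 1, but the housekeeping list lost its call (adjusted p = 0.0521) and the fibroblast, endothelial and epithelial markers gained one (adjusted p = 0.0280). Lists falling with time (3) numbered 1 without background correction, 6 with median centring, 0 with an estimated correlation, 1 with fry, 1 with the term and 1 to 3 without 1 array. Lists rising (1) numbered 2 with median centring, 0 with Agilent's ratios, 0 with the deposited ratios, 2 with the strict filter, 0 with an estimated correlation, 0 with fry and 0 to 3 without 1 array. Over its alternatives the adjusted p ranged from 6.53e-13 to 0.363 for the fall of interferon-stimulated genes, from 4.19e-08 to 0.988 for the lower JAK-STAT feedback list, from 4.48e-06 to 0.988 for lower interferon-stimulated genes and from 5.96e-06 to 0.988 for the higher housekeeping list. For change with time it ranged from 5.92e-04 to 0.947 for the feedback list, from 2.23e-04 to 0.947 for the pathway components and from 3.53e-09 to 0.995 for NF-kB targets. In 4 lists the direction turned, with adjusted p of 0.00837 for the plasma cell list (mean) and 0.0109 for the housekeeping list (change with time) with median centring, 0.662 for the feedback list without 1 h and 0.995 for NF-kB targets without 24 h (change with time).

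Genes at least 2-fold apart numbered 464, 167, 1519 and 349 at 1, 3, 6 and 24 h. They were 9354, 4782, 5340 and 5747 with median centring, 2805, 1666, 4330 and 2346 with Agilent's ratios and 2918, 1660, 4322 and 2345 with the deposited ratios. Without background correction they were 77 at 3 h (92.2% lower against 60.5%) and 184 at 24 h (70.7% against 53.6%), with an offset of 16 they were 376 (31.9%) and 601 (35.3%), and with the strict filter 107 at 3 h (94.4%). The share lower was 0.139%, 0.230%, 1.05% and 0.870% with median centring against 35.1%, 60.5%, 21.8% and 53.6%, and with Agilent's ratios 17.6% at 3 h and 17.2% at 24 h. With the deposited ratios it was 17.6% and 17.2%, and with the strict filter 70.2% at 24 h.

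With median centring the median of all genes was 0.776, and 31 genes given by the rule for named genes that passed in this fit or with loess turned above 0, of which 25 returned to their direction relative to that median. Those reported had mean log2 ratios of 0.012 for BBC3, 0.33 for BCL10, 0.87 for BCL3, 0.46 for BCL6, 0.28 for BIRC2, 0.038 for BIRC3, 0.51 for CCNG2, 0.19 for CDKN1B, 0.17 for ELL3, 0.67 for JAK1, 0.75 for JAK2, 1.03 for JAK3, 0.20 for KDM4A, 0.48 for KDM4C, 0.0039 for KLF6, 0.11 for LMO2, 0.69 for LYN, 0.81 for MCL1, 0.68 for MYC, 0.93 for NFKBIA, 0.50 for NIP7, 0.45 for PDIA3, 0.17 for PFKFB3, 0.41 for PLSCR1, 0.71 for PRDM1, 0.69 for PTPRC, 0.60 for SAMD9, 0.46 for TLR1, 0.93 for TMED9 and 0.87 for TNFAIP3. Genes and lists that passed in neither fit and changed sign are not listed.

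Signal over background limits the ratios of dim spots. Of the probes on an array, 39.4% to 44.8% were well above background in the DMSO channel, and with only probes well above background in both channels on all 4 arrays 12082 of 18516 genes remained, with 305 lower.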

Other observations

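The tests of the component and of the housekeeping list below were chosen after the results were seen, and the lists in this paragraph were picked after their values were seen. Several lists stood apart on single arrays without a called mean over the times. MHC class I and antigen processing genes had medians of 0.41 at 1 h and 0.44 at 6 h, at percentiles 99.95 and 99.78 of 10000 matched random lists, and glycolysis and hypoxia genes 0.29 and 0.33, at percentiles 99.73 and 99.26. These are the 2 arrays that stood apart (next paragraph), and at 3 h and 24 h the lists were at percentiles 84.72 and 73.77, and 40.46 and 75.2. At 6 h the heat shock genes had a median of -0.27, at percentile 1.12, and at 24 h one of 0.19, at percentile 97.43. On the 24 h array the MYC-driven ribosome biogenesis genes had a median of 0.16 (percentile 99.82), S phase genes 0.14 (percentile 99.05) and chemokine and cytokine genes 0.32 (percentile 99.96). At 3 h the NF-kB targets had a median of -0.25, at percentile 0. Each value comes from 1 array and was not tested.

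The 1 h and 6 h arrays shared a component that the 3 h and 24 h arrays lacked, taken per gene as the mean of the first pair minus that of the second (SD over genes 0.38). Their ratios correlated at 0.65 across genes, against 0.50 to 0.51 for simulated unchanged genes with a shared control, with a covariance of 0.147 against 0.115 simulated. The simulation set the spread in the control equal to that in the treated sample. A larger spread in the control would give a higher correlation, so this comparison cannot show an excess over a shared control. Genes are not independent replicates, and part of any correlation may come from a shared DMSO sample. An AZD1480 effect present at 1 h and 6 h only is argued against, because across genes the component correlated more with the difference in the Cy3 channel (-0.75) than with that in the Cy5 channel (0.34), a gap in size of 0.41. Base composition of the probes or templates cannot be told apart from other causes: the median component was 0.12 for 4121 genes on chromosomes 16, 17, 19, 20 and 22, which are rich in G and C, and -0.02 for 4446 genes on chromosomes 3, 4, 5, 6, 13 and X, a difference of 0.14 (permutation p = 1e-04, the smallest that 10000 permutations can give). This lay between the sizes set for and against it, and base content of the probes was not analysed here.

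The housekeeping and ribosomal protein list was higher with AZD1480 at each time. Brightness between the 20 intensity bins does not account for this, since the list's median was at percentile 100 of random lists matched by bin. Brightness within a bin was not matched, so an effect of brightness inside a bin stays open. The component of the 1 h and 6 h arrays does not account for the higher level of the list. The lower of the list's percentiles on the 3 h and 24 h arrays was 99.99. A gene-specific dye effect stays open, with no dye swap to remove it: the lowest percentile over the 4 arrays was 99.95, as such an effect would give, and the change from 3 h to 24 h had a median of -0.0038. The change from 1 h to 6 h, 0.21, lay just outside the middle 95% of matched random lists, at percentile 97.54. A dye effect, an effect of brightness inside a bin and a higher level of these transcripts in treated cells therefore cannot be told apart.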
